A study of Mus musculus with 4 samples.

How the data were processed

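Splenic CD8 T cells of female C57BL/6 mice were profiled 24 h after an intraperitoneal injection of TCDD at 10 µg/kg or of the solvent DMSO. TCDD is a persistent dioxin and a ligand of the aryl hydrocarbon receptor (AHR). Per the labels' protocols the mice were 8 to 12 weeks old, spleen cells were sorted by FACS to a purity above 99%, RNA was taken with TRIzol, and it was amplified with a MessageAMP kit before Affymetrix labelling and hybridisation. Per the design text 4 mice were used for a group and their cell suspensions were pooled. It does not say whether the 2 arrays of a group came from separate pools, so the p-values measure the spread between these arrays, which may be technical.

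The deposited table gives 1 log2 expression value per probe set and array for 4 arrays, 2 from TCDD-treated and 2 from DMSO-treated mice. Per the submitters' processing notes the authors made these values with RMA, and its version is not given in the sources used here. The log2 scale was read from the values, which ran from 3.09 to 14.62 and were rounded to 2 decimals. RMA as usually run corrects background, quantile normalises the arrays and summarises the probes of a probe set. These log2 values have no true zero, and an RMA value near the low end does not separate weak expression from none. Array medians were 5.97 and 6.03 for the TCDD arrays and 5.99 and 6.01 for the DMSO arrays. The number of arrays limits the precision of every comparison.

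Of 22690 probe sets, 64 were Affymetrix controls and were left out of the tests, which leaves 22626. Genes were named from the platform annotation, with symbols updated through Entrez identifiers in a RefSeq table of the mouse assembly GRCm38.p6, from which no coordinate was used. In all, 20380 probe sets had 1 gene symbol, 691 had several and 1555 were unnamed here. Names were taken only from probe sets with 1 symbol. They cover 12393 genes, of which 4956 had more than 1 probe set. Each gene is represented by its probe set with the highest mean over the 4 arrays.

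Differences are TCDD minus DMSO on the log2 scale. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, no filter), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Intervals are 95% limits from the same moderated fit. A permutation test of 2 arrays against 2 cannot give a two-sided p below 0.3333, so none is printed for single genes. Gene lists were tested with limma's camera at its preset correlation of 0.01, on 1 probe set per gene, with adjustment over 31 lists. These lists, 21 of pathways or T cell programmes and 10 of markers of other cell types, held 731 gene entries, of which 618 were measured. Camera was run again with the correlation estimated from the data, and fry was run as a second set test. With 4 arrays the estimated version rests on few residual degrees of freedom and has little power. For the T cell receptor and CD8 list the unadjusted camera p rose from 3.283e-05 to 0.04506, although its estimated correlation was −0.03258. A call lost there does not by itself show that correlation between genes made the call.

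Lists, tests, the rule for named genes and all alternatives except those named below as added were fixed before the data were examined. The rule names Cyp1a1, Cyp1b1, Ahrr, Tiparp, Nqo1 and any other AHR target gene with a difference above 0.5 in size. It also names up to 12 higher and 12 lower genes past the threshold. Where fewer passed, it fills each direction to 12 by the size of the difference, among genes with an unadjusted p under 0.05, both TCDD arrays beyond both DMSO arrays and a mean above the median level of 6.01. From each list it names the 2 to 4 members with the largest differences among those above that median. The choice within that range, 4 for the AHR target list and the lists that passed camera and 2 for the others, was made after the values were seen. The rule gave 92 genes.

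The alternatives were a centring of each array on its median, a further quantile normalisation, filters at the 25th percentile and at the median of the mean level, a variance trend with robust fitting, array weights, removal of probe sets whose names mark possible cross hybridisation, the mean of a gene's probe sets, a replicate block, a fold rule with no test, and each array left out in turn. The 2 other splits of the 4 arrays, and the estimated correlation for lists that passed for gene means or with an array left out, were added after seeing the data. A replicate left out leaves 1 array in its group, which is then assumed to vary like the other group.

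The limma step was tested on simulated data for the comparison of TCDD with DMSO, with 22626 probe sets, 10 runs and 200 changed probe sets in each. It called 0.4% of those changed 1.5-fold, 11.4% of those changed 2-fold, 83.2% of those changed 4-fold and 93.8% of those changed 8-fold, with a mean of 4.9 false calls in a run. Camera, tested over 12393 genes with lists of 20 genes moved by 0.25, found 100% of them and called 1% of the unchanged lists. The simulated noise was independent between genes. In the arrays the estimated correlation was 0.5368 for the immediate early and dissociation list, so the rate of 1% does not carry over to such lists.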

Results

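Gene expression was measured in sorted splenic CD8 T cells 24 h after mice received the AHR ligand TCDD or its solvent DMSO, with 2 arrays per group. The study's title names the effect of TCDD on these cells as its subject. The closest pair of arrays shared a replicate number and not a treatment. Over all probe sets the Pearson correlation was 0.9932 between TCDD replicate 1 and DMSO replicate 1, 0.9829 between TCDD replicate 2 and DMSO replicate 2, 0.9816 between the TCDD arrays and 0.9853 between the DMSO arrays. Of the pairs that shared neither, TCDD replicate 2 with DMSO replicate 1 had 0.988, above the pair numbered 2, and TCDD replicate 1 with DMSO replicate 2 had 0.9806. The SD of the log2 differences between the arrays of a group was 0.34 for TCDD and 0.30 for DMSO. It was 0.20 between TCDD and DMSO replicate 1, and 0.32 between TCDD and DMSO replicate 2.

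For 4 genes of the classical AHR battery, Cyp1a1, Cyp1b1, Ahrr and Nqo1, no difference with TCDD was detected. Cyp1a1, the cytochrome P450 that is the standard readout of AHR activation, measured 6.19 ± 0.085 (SD, n = 2) after TCDD and 6.24 ± 0.127 (n = 2) after DMSO. The difference was −0.05, with 95% limits of −0.37 and 0.27, so a rise in its signal above 1.204-fold lay outside the interval. Cyp1b1, another P450 of the battery, differed by −0.155, with an upper fold limit of 1.093. Ahrr, which encodes the repressor of the receptor, differed by 0.03 with an upper fold limit of 1.239, and the quinone reductase gene Nqo1 differed by −0.045 with an upper fold limit of 1.221. The probe sets of Cyp1b1, Ahrr and Nqo1 had means below the median of all probe sets, where RMA values compress differences. That of Cyp1a1 was little above this median of 6.01, so its interval bounds the signal, and a rise in transcript may be compressed there too. Tiparp, an AHR target that encodes a mono-ADP-ribosyltransferase, was well above that level, at 10.21 and 8.18 in TCDD replicates 1 and 2 against 9.06 and 7.78 in the DMSO replicates. It was higher after TCDD within both numbers, by 1.15 and 0.40, and lower in the arrays numbered 2 than in those numbered 1 of the same treatment. Its difference of 0.775, fitted without the number, had limits of −1.28 and 2.83 and turned to −0.24 without TCDD replicate 1, and its other probe sets differed by 0.075 and 0.17. Nfe2l2, which encodes the oxidative stress regulator NRF2, was lower in both TCDD arrays, at 5.54 and 5.38 against 6.14 and 6.80. Its difference of −1.01 had an unadjusted limma p of 0.009746 and did not pass the adjustment (adjusted p = 0.9973). Among members with more signal, the leupaxin gene Lpxn differed by −0.215 and the lysosomal transporter gene Slc46a3 by −0.065.

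Over the 13 measured AHR target genes the mean difference was −0.067 and the median −0.05. Both TCDD arrays lay above both DMSO arrays for 1 member and below for 4, and the groups overlapped for 8. The limma test called 0 members over all genes tested and 0 adjusted over the list alone, and camera did not pass (adjusted p = 0.2024, and 0.9744 with an estimated correlation). The list's mean turned to 0.01 without TCDD replicate 2 and to 0.111 over members above the median level, and without DMSO replicate 2 it was −0.10 and passed camera (adjusted p = 0.04037, and 0.9522 with an estimated correlation). The 15 measured genes of the list for the AHR complex and its cofactors had a mean difference of −0.033 (camera adjusted p = 0.891). Among them the corepressor gene Nrip1 was at −0.595 and Hsp90b1 at −0.56. Hsp90b1 encodes the HSP90 paralogue of the endoplasmic reticulum, not the cytosolic HSP90 of the complex. The 17 genes of the NRF2 oxidative stress list had a mean of −0.106 (camera adjusted p = 0.2024), with the thioredoxin gene Txn1 at −0.67 and the glutathione peroxidase gene Gpx1 at −0.46.

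**Figure D1:**
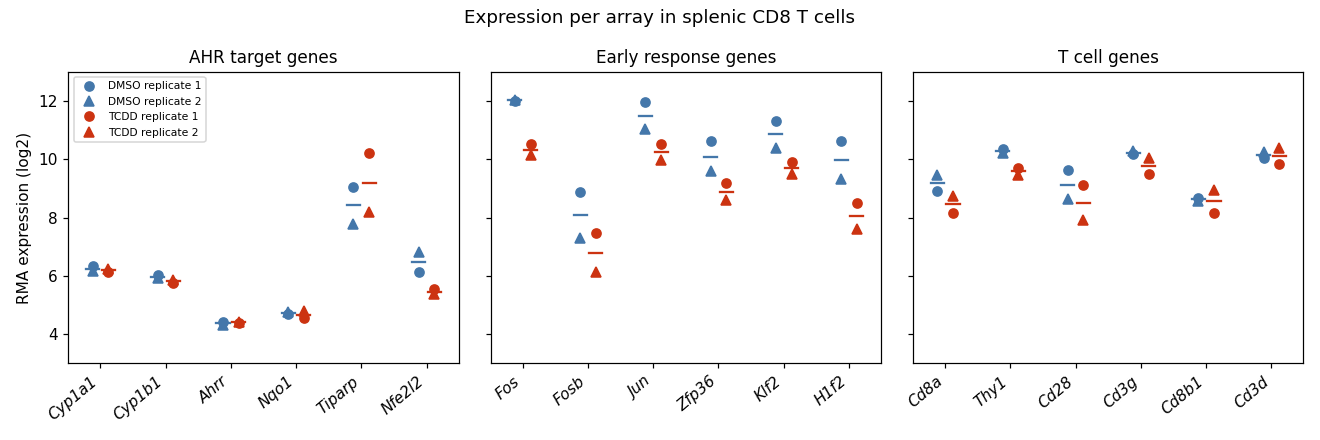
RMA expression (log2, y axis) of named genes in each array, with DMSO in blue, TCDD in red, circles for replicate 1, triangles for replicate 2 and bars for the mean of the 2 arrays. Cyp1a1 lies between 6.13 and 6.33 in all 4 arrays, while Fos lies at 10.51 and 10.13 after TCDD and at 12.00 and 12.03 after DMSO.

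Fos, Jun and Zfp36, genes of the early response, measured lower in both TCDD arrays than in both DMSO arrays. Fos, a subunit of the AP-1 transcription factor, measured 10.32 ± 0.269 (SD, n = 2) after TCDD and 12.02 ± 0.021 (n = 2) after DMSO, a difference of −1.695 with 95% limits of −2.11 and −1.28. Its AP-1 partner Jun differed by −1.25, while its other probe set differed by −0.54 with overlapping groups. Zfp36, which encodes an mRNA decay factor for cytokine transcripts, differed by −1.205. Fosb measured 7.46 and 6.12 after TCDD against 8.88 and 7.30 after DMSO, a difference of −1.30. Over the 24 measured genes of the immediate early and dissociation list the mean difference was −0.41 and the median −0.31. Both TCDD arrays were lower for 7 members and higher for 1, and the groups overlapped for 16. The list passed camera (adjusted p = 0.0003739) and lost the call with an estimated correlation (adjusted p = 0.9744). The limma test called 0 members over all genes tested and 1, Fos, adjusted over the list alone (adjusted p = 0.004087). The list differed by −0.40 between the arrays numbered 1 and by −0.43 between those numbered 2. It was far lower in the arrays numbered 2 of both treatments, at 8.28 and 8.70 against 9.25 and 9.65, so the left-out values turned: 0.076 without TCDD replicate 2 and 0.063 without DMSO replicate 1. As arrays were left out, Fos, Jun and Zfp36 ranged from −1.885 to −1.505, −1.715 to −0.785 and −1.72 to −0.69. Their sign could not turn there, because both TCDD arrays lay below both DMSO arrays.

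Cd8a, Thy1 and Cd3g, genes of T cell identity, also measured lower in both TCDD arrays than in both DMSO arrays, and none passed limma. The coreceptor gene Cd8a differed by −0.73, at 8.17 and 8.74 after TCDD against 8.91 and 9.46 after DMSO, and its other named probe set by −0.50. The surface glycoprotein gene Thy1 differed by −0.70 (95% limits −1.045 and −0.355), the costimulatory receptor gene Cd28 by −0.63 and the T cell receptor complex gene Cd3g by −0.45. Cd28 had overlapping groups and ran from −1.23 to −0.03 as arrays were left out, and Cd3g ran from −0.71 to −0.19. The difference was uneven within the complex. Cd3d at −0.055, Cd8b1 at −0.07 and Lat at 0, chosen after their values were seen, had overlapping groups. Over the 21 measured genes of the T cell receptor and CD8 identity list the mean difference was −0.235, with −0.22 and −0.25 within the numbers. Both TCDD arrays were lower for 6 members and higher for 0, and the groups overlapped for 15. Camera passed (adjusted p = 0.0005089), and the call was lost with an estimated correlation (adjusted p = 0.9744) and without TCDD replicate 1 (−0.23, adjusted p = 0.09905). No member passed limma over all genes tested or adjusted over the list alone.

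The 16 measured genes of the naive and memory T cell list had a mean difference of −0.20 and passed camera narrowly (adjusted p = 0.04508, and 0.9744 with an estimated correlation). Klf2, a quiescence factor that maintains expression of homing receptors, differed by −1.17 and Igfbp4 by −0.475, while Foxp1, which encodes another quiescence factor, differed by 0.46. The transcription factor gene Foxo1 was at −0.535 by the probe set used here, and its 3 other probe sets above the median level went the other way. Both TCDD arrays were lower for 4 members and higher for 1, with overlap for 11, and limma called 0 over all genes tested and 0 adjusted over the list alone. The list lost its call without TCDD replicate 1 (mean −0.28, adjusted p = 0.07512), without TCDD replicate 2 (−0.125, adjusted p = 0.5917) and without DMSO replicate 2 (−0.16, adjusted p = 0.3093).

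Effector and activation genes did not pass in the main fit. With the replicate block the cytotoxic list passed camera (adjusted p = 0.02937, and 0.9007 with an estimated correlation). The 27 cytotoxic effector genes had a mean of −0.12 (camera adjusted p = 0.09), with the T-box factor gene Tbx21 at −0.74 and the granzyme gene Gzma at −0.585. Gzma measured 10.07 in DMSO replicate 2 and between 7.37 and 8.78 elsewhere. The cytotoxic list was at −0.033 without DMSO replicate 2, and passed camera at −0.206 without DMSO replicate 1 (adjusted p = 0.03529) and for gene means (adjusted p = 0.04808). With an estimated correlation these were lost (adjusted p = 0.929 and 0.9413). The 24 T cell activation genes had a mean of −0.018 (adjusted p = 0.7731), with the activation-induced factors Egr1 at −0.96 and Nr4a1 at −0.745. Both had overlapping groups, and Egr1 ran from −1.785 to −0.135 as arrays were left out. The 26 interferon response genes had a mean of −0.04 (adjusted p = 0.891), with Ifi47 at −0.75 and Ifit2 at −0.475. The 19 heat shock genes had a mean of −0.22 (adjusted p = 0.2024). The inducible chaperone genes Hspa1a and Hspa1b differed by −1.89 and −1.79, and their highest values, 9.14 and 11.94, were both in DMSO replicate 2. Without that array the heat shock list was at −0.20 and passed camera (adjusted p = 0.01503, and 0.9522 with an estimated correlation). It was at −0.081 without TCDD replicate 2 (adjusted p = 0.9811) and at −0.351 without TCDD replicate 1, and passed for gene means (adjusted p = 0.00333, and 0.9413 with an estimated correlation). None of these 4 lists had a member past limma, over all genes tested or adjusted over the list alone.

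The other 11 pathway lists had mean differences between −0.051 and 0.064, with camera adjusted p of 0.4856 or more, and 0 members past limma. These covered regulatory T cell genes (0.009), glucocorticoid response (0.005), circadian clock (0.064), apoptosis (−0.033), cell cycle (−0.009), chemokine receptors and adhesion (−0.024), glycolysis (−0.051), oxidative phosphorylation (−0.02), cytosolic ribosomal proteins (−0.034), cholesterol synthesis (−0.021) and NF-kB targets (0.042). Without DMSO replicate 2 the cell cycle list passed camera at −0.086 (adjusted p = 0.01808, and 0.9522 with an estimated correlation). Their members with the largest differences included the integrin gene Itgae at 0.345, the TGF-beta receptor gene Tgfbr2 at −0.24, the MAP kinase phosphatase gene Dusp1 at −0.825 and Errfi1 at 0.345. Among clock genes Bhlhe40 differed by 0.645 and Nr1d2 by −0.52. The antiapoptotic gene Mcl1 differed by 0.31 and the death receptor gene Tnfrsf1a by −0.255, while the replication genes Pcna and Mcm4 differed by −0.50 and −0.38. The chemokine receptor gene Ccr9 was at 0.415 and Cd47 at −0.41. The glucose transporter gene Slc2a1 was at 0.655 and the lactate transporter gene Slc16a1 at −0.61. Subunits of respiratory complex I went both ways, with Ndufs1 at −0.645 and Ndufv2 at 0.485. The ribosomal protein genes Rpl27a and Rpl12 differed by −0.555 and −0.475, and the sterol synthesis genes Hmgcs1 and Fdft1 by 0.305 and 0.21. The NF-kB targets Traf1 and Icam1 differed by −0.46 and 0.355.

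Of the 10 lists of markers of other cell types, 0 passed camera. Dendritic cell markers had the highest mean (0.13, adjusted p = 0.2058), with Irf8 at 0.775 and Naaa at −0.425, and passed camera for gene means at 0.159 (adjusted p = 0.00333, and 0.9413 with an estimated correlation). B cell markers followed at 0.115 (adjusted p = 0.9393), with the MHC class II genes H2-Eb1 at 0.685 and H2-Aa at 0.635. Monocyte and macrophage markers were at 0.052 (adjusted p = 0.891), with the lysozyme gene Lyz2 at 0.555. Neutrophil markers were lowest at −0.24 (adjusted p = 0.1329), with the calprotectin gene S100a8 at −1.315 and Camp at −0.25, and S100a8 measured 8.67 in DMSO replicate 2 against 5.45 to 5.94 elsewhere. Plasma cell markers were at −0.082 (adjusted p = 0.891), with Jchain at −0.63 and Xbp1 at −0.21. Without DMSO replicate 2 the dendritic, B cell, neutrophil and plasma cell means turned to −0.062, −0.056, 0.081 and 0.072. The other 5 lists were NK cell (−0.002), CD4 T cell (0.002), erythroid (0.01), megakaryocyte and platelet (−0.012) and stromal and endothelial markers (0.044), with adjusted p of 0.5015 or more. Their named members were Tyrobp (0.195), Cd40lg (0.18), Tnfsf8 (−0.18), Klf1 (0.145), Epor (−0.11), Itgb3 (−0.125), F2rl2 (0.075), Acta2 (0.26) and Tagln (−0.155). Without DMSO replicate 2, NK cell markers at 0.167 and monocyte and macrophage markers at 0.18 passed camera (adjusted p = 0.01503 for both, and 0.9522 for both with an estimated correlation). Without DMSO replicate 1, neutrophil markers passed at −0.562 (adjusted p = 6.413e-05, and 0.929 with an estimated correlation).

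**Figure D2:**
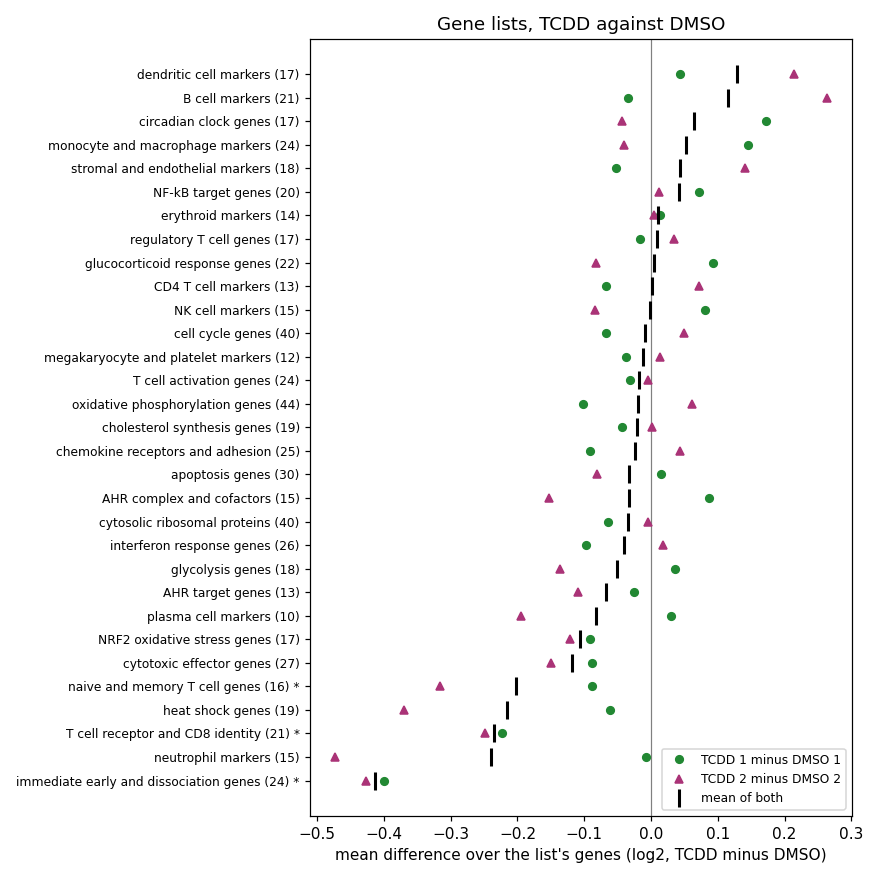
Mean difference over the measured genes of each of the 31 lists (log2, TCDD minus DMSO, x axis), within the arrays numbered 1 (green circles), within those numbered 2 (purple triangles) and over both (black bars), with the number of measured genes in brackets and a star where camera at its preset correlation passed. The 3 starred lists lie below 0 in both numbers, and the star is lost for all 3 with an estimated correlation.

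Across the whole array 0 of 22626 probe sets passed the limma test (lowest adjusted p = 0.9973). At an unadjusted p under 0.05 there were 439, of which 182 were higher and 257 lower after TCDD, where chance gives 1131. Both TCDD arrays lay beyond both DMSO arrays for 5774 probe sets, or 25.52%, below the 33.33% that chance gives. Of these, 4 probe sets were at least 2-fold higher and 22 at least 2-fold lower.

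The largest differences among genes with separate groups, an unadjusted p under 0.05 and a mean above the median level, none of which passed the adjustment (adjusted p = 0.9973 for all), were as follows. On the higher side Lyz1, which encodes lysozyme, differed by 1.11, but by 0.10 without probe sets marked for cross hybridisation. Lgals3, which encodes galectin-3, differed by 1.06, at 8.09 and 7.60 after TCDD against 6.99 and 6.58 after DMSO. The deubiquitinase gene Zranb1 differed by 1.04 and the BBSome component gene Bbip1 by 0.76, with limits of 0.46 and 1.06. The other probe sets of Zranb1 differed by 0.335 and 0, with overlapping groups. The others on this side were Hacd3 (0.75), Fbxo22 (0.735), Afp (0.695), Mrps9 (0.69), the proteasome subunit gene Psmd6 (0.66), Erbin (0.66), Rexo4 (0.625) and the RNA polymerase III subunit gene Polr3a (0.605). The other probe sets of Afp, all below the median level, differed by between −0.09 and 0. On the lower side the linker histone gene H1f2 differed by −1.92, at 8.50 and 7.59 after TCDD against 10.62 and 9.31 after DMSO, ahead of Fos, Jun, Zfp36 and Klf2. The other probe sets of H1f2 differed by −1.215 and, with overlapping groups, by −0.085. The translation factor genes Eif4a2 and Eif3m differed by −1.07 and −0.875, and the condensin gene Smc4 by −0.98. These differences lay mostly in the arrays numbered 2. Within numbers 1 and 2 they were −0.44 and −1.70 for Eif4a2, −0.24 and −1.51 for Eif3m, and −0.39 and −1.57 for Smc4. The remaining genes were Zfp638 (−0.93), Eef1e1 (−0.865), Zkscan3 (−0.835) and Cnbp (−0.835). Without probe sets marked for cross hybridisation Zkscan3 was at −0.02. These 24 came from 89 higher and 138 lower genes that met the same criteria. Of all 92 named genes, 31 had another probe set above the median level. For 11 of these at least 1 such probe set went the other way, among them Fbxo22, Mrps9, Erbin, Rexo4, Foxo1, Foxp1, Mcl1 and Ccr9. For Fbxo22, Mrps9 and Rexo4 that value was near 0, at −0.005, −0.02 and −0.005.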

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

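The tests of RNA integrity, of handling, of the uneven strength of the number-linked programme and of the share of T cells below were chosen after their results were seen. The test of the trend on the number difference was set before.

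Among the 64 control probe sets, which enter no comparison, 5 had both TCDD arrays above both DMSO arrays, where chance gives 10.667. These were 3 for the B1 and B2 repeat elements of the mouse genome, with differences of 0.25, 0.425 and 0.135 on the log2 scale, 1 for pyruvate carboxylase at 0.11 and 1 for a bacterial trp spike probe set at 0.105. Only 1 control probe set lay lower in both TCDD arrays.

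The early response list had a mean difference of −0.40 and −0.43 within the 2 numbers, and its camera call was lost with an estimated correlation (adjusted p = 0.9744) and by fry (adjusted p = 0.9722), with means of 0.076 without TCDD replicate 2 and 0.063 without DMSO replicate 1. The programme that separates arrays 1 from arrays 2, if of even strength, is argued against as the whole cause, since each number holds 1 array of each treatment. The trend of the treatment difference on the number difference across genes predicts a shift of 0.156, opposite to the observed −0.41. That trend decides nothing, as the bound set beforehand allowed only for small shifts and was not met. Its slope also depends on how far 2 pairs of arrays spread, whatever spread them. The SD of their differences was 0.346 for TCDD replicate 1 with DMSO replicate 2 and 0.271 for TCDD replicate 2 with DMSO replicate 1. An uneven strength of that programme is argued against only if it was shared by all its genes. The 75 other genes at least 2-fold higher in the arrays numbered 1 had a mean treatment difference of 0.158, opposite to the list. Of these, 52 were higher and 23 lower after TCDD. The 95% limits of that mean, 0.058 and 0.259, are over genes, which are not independent. The list's own members were left out, so a strength that differed between them and those genes stays open. RNA integrity stays open, since the 3 prime minus 5 prime signal differed between treatments by 0.02 on average, within number 1 by 0.08 for Gapdh and −0.08 for actin, and within number 2 by 0.26 and −0.18. Handling of the spleens stays open, as the heat shock list, also raised by handling, had a mean of −0.216 that did not pass camera (adjusted p = 0.2024, and 0.9744 with an estimated correlation), and an effect of TCDD stays open and untested.

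The T cell receptor and CD8 list had both TCDD arrays below both DMSO arrays for 6 of 21 members and overlap for 15, and its camera call was lost with an estimated correlation (adjusted p = 0.9744). A lower share of T cells would raise the markers of the cells that took their place, which need not be of every type, so a count of lists decides little. Of the 10 marker lists 6 had a mean above 0, of which CD4 T cells, at 0.002, are T cells themselves and need not rise. The highest and lowest of them, dendritic cells at 0.13 and neutrophils at −0.24, differed by permutation of genes (p = 0.0019). That p is too small, since the 2 lists were picked as the extremes of 10. The permutation also treats genes as independent, while the neutrophil list had an estimated correlation of 0.4662. Without DMSO replicate 2 neutrophils were at 0.081, and the highest and lowest lists, then monocytes and macrophages at 0.18 and dendritic cells at −0.062, did not pass the same permutation test. By these tests the share of T cells cannot be told apart from lower expression per cell. Per the labels the sort reached above 99% purity, which would leave few other cells. The MHC class II genes of the B cell list nevertheless had high signal. H2-Aa measured 11.30 and 10.42 after TCDD and 10.94 and 9.51 after DMSO, and H2-Eb1 10.17 and 9.39 against 9.94 and 8.25. Other cells may have contributed more than the stated purity implies, which was not tested. Of the 159 measured entries in the marker lists, 87 were above the median level in these arrays and 18 were also in another list, which blunts the test.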

How the results depend on the processing

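The splits of the 4 arrays by the number in their titles and across it, and the estimated correlation for gene means or with an array left out, were chosen after seeing the data, and every other setting was set before. Of the 92 named genes, 64 kept their direction in every setting run, 21 higher and 43 lower, and no named gene passed the adjusted threshold in any. Where both TCDD arrays lay beyond both DMSO arrays, leaving an array out cannot turn the sign. The naming rule asked for that separation in the genes that filled each direction, so their kept direction is partly fixed by the choice. With only 2 arrays per group, and signal over background not given, small differences of dim genes such as Cyp1a1, Cyp1b1, Ahrr and Nqo1 are the least certain. The limma count of 0 probe sets after TCDD was 0 under every normalisation, filter, variance model and left-out array. The fold rule with no test gave 26. The split by number gave 1, Rgs1, and the crossed split gave 0. With the replicate block it was also 0, with 612 probe sets at an unadjusted p under 0.05 against 439 without it, and other settings gave 116 (without DMSO replicate 2) to 1079 (without TCDD replicate 1), with 203 above the median level and 205 for gene means. The same-numbered arrays deviated together with a correlation of 0.234 across probe sets, but the labels give these numbers no shared batch. The share of probe sets with separate groups was 27.58% after centring, 27.65% after quantile normalisation again, 24.12% above the median level, 24.92% above the 25th percentile and 24.78% for gene means, against 25.52%.

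The AHR target mean turned to 0.111 for probe sets, or for list members, above the median level, and ranged from −0.144 to 0.01 as arrays were left out. The number of pathway lists past camera, 3 at first, was 5 for gene means, 0 with an estimated correlation and 0 by fry, and it changed as arrays were left out. The number of other cell type lists past it, 0 at first, was 1 for gene means, dendritic cells, and 1 with the replicate block, where neutrophil markers passed, and 0 to 2 as arrays were left out. With the block cytotoxic effector genes also passed (adjusted p = 0.02937), and 0 lists did so with an estimated correlation. The naive and memory list lost its call under 11 of the settings set before, and the T cell receptor list under 3. Every list that passed for gene means or with an array left out lost its call there with an estimated correlation, which has little power with so few arrays. Without probe sets marked for cross hybridisation Foxo1 turned to 0.165, Mcl1 to −0.145, Ccr9 to −0.185, Lyz1 moved from 1.11 to 0.1, Zkscan3 from −0.835 to −0.02, and the regulatory T cell list turned to −0.004 and the NK cell list to 0.018. For gene means Hmgcs1 turned to −0.142 and the NK cell list to 0.008. For these the change of probe set is the cause. Above the median level, by either filter, the glucocorticoid list was at −0.007 and the cholesterol list at 0.047, the NK cell list was at 0.003 above the 25th percentile, and the oxidative phosphorylation list was at 0.005 after quantile normalisation. For the filters the loss of members is the cause, as the differences of the members that stay do not change. The cause was not tested for the quantile normalisation. Leaving an array out, as below, also leaves the numbers unbalanced between the treatments. The early response list turned through its number difference, as given in the results, and the cause was not tested for the other turns below.

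Left-out arrays turned the sign of some uncalled genes, given as the lowest and highest value over the 4 arrays left out and grouped by the array whose loss gave the end of opposite sign. Without DMSO replicate 1 these were Cyp1a1 (−0.14 to 0.04), Slc46a3 (−0.17 to 0.04) and Nr4a1 (−1.77 to 0.28). Without DMSO replicate 2 these were Ahrr (−0.025 to 0.085), Gzma (−1.935 to 0.765), Rpl27a (−1.115 to 0.005), Icam1 (−0.055 to 0.765), H2-Eb1 (−0.16 to 1.53), H2-Aa (−0.08 to 1.35), Jchain (−1.91 to 0.65), S100a8 (−2.925 to 0.295), Irf8 (−0.355 to 1.905) and Tnfsf8 (−0.47 to 0.11). Without TCDD replicate 1 these were Tiparp (−0.24 to 1.79), Nqo1 (−0.165 to 0.075), Errfi1 (−1.065 to 1.755), Bhlhe40 (−0.1 to 1.39), Slc2a1 (−0.065 to 1.375) and Tagln (−0.49 to 0.18). Without TCDD replicate 2 these were Lpxn (−0.49 to 0.06), Tgfbr2 (−0.565 to 0.085), Nr1d2 (−1.5 to 0.46), Pcna (−1.015 to 0.015) and F2rl2 (−0.005 to 0.155).

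The means of lists turned in the same way. Without DMSO replicate 1 they were T cell activation (−0.289 to 0.252), cell cycle (−0.086 to 0.068), chemokine receptors and adhesion (−0.096 to 0.048) and monocyte and macrophage (−0.076 to 0.18). Without DMSO replicate 2 they were B cell (−0.056 to 0.286), plasma cell (−0.235 to 0.072), neutrophil (−0.562 to 0.081), dendritic cell (−0.062 to 0.321) and NK cell (−0.17 to 0.167). Without TCDD replicate 1 they were interferon response (−0.148 to 0.068), glucocorticoid response (−0.275 to 0.286), circadian clock (−0.112 to 0.241), oxidative phosphorylation (−0.132 to 0.092), NF-kB target (−0.08 to 0.165), erythroid (−0.005 to 0.024) and megakaryocyte and platelet (−0.081 to 0.057). Without TCDD replicate 2 they were AHR complex and cofactors (−0.175 to 0.109), regulatory T cell (−0.019 to 0.036), immediate early and dissociation (−0.902 to 0.076), apoptosis (−0.104 to 0.038), glycolysis (−0.131 to 0.029), CD4 T cell (−0.095 to 0.1) and stromal and endothelial (−0.046 to 0.135).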

Other observations

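The test of handling below was chosen after its result was seen, as were the genes named here. The test of the normalisation was set before. The arrays numbered 1 and 2 differed more than the treatments did. A log2 difference of at least 1 with separate groups was found for 85 genes higher in the arrays numbered 1 and 20 higher in those numbered 2, against 3 higher and 11 lower after TCDD. Rgs1, a regulator of G protein signalling that is induced on lymphocyte activation, measured 9.94 in both arrays numbered 1 and 6.56 and 6.68 in those numbered 2, a difference of −3.32 (number 2 minus number 1, limma adjusted p = 0.01768). It was the 1 probe set that passed in this split, with 1688 at an unadjusted p under 0.05, and the blocked fit of treatment passed 0. Also higher in both arrays numbered 1, without passing, were Maff (−2.81), Ctla4 (−2.725), Pmaip1 (−2.525), Klf10 (−2.51), Nfkbiz (−2.44), Atf3 (−2.275), Nr4a2 (−2.115), Klf6 (−2.095), Per1 (−2.025), Irf4 (−1.54) and Cxcr4 (−1.68). Zfand2a (−2.43), Tubb2a (−2.295), Vps37b (−2.275), Ubl5 (−2.14), Tiparp (−1.655) and Errfi1 (−2.185) were higher there as well.

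Some single genes were higher in both arrays numbered 2, without passing. Igha, the heavy chain gene of IgA, measured 8.85 and 10.06 in the arrays numbered 2 against 7.09 and 6.97. S100a9 measured 5.63 and 7.80 against 5.0 and 4.61, and Jchain 6.60 and 8.04 against 5.66 and 5.48. The marker lists of other cell types went both ways (number 2 minus number 1). They ran from −0.298 for dendritic cells and −0.193 for B cells to 0.255 for NK cells and 0.41 for neutrophils. Actb, the cytoplasmic actin gene, measured 12.01 and 12.45 against 10.32 and 10.79. The mean 3 prime minus 5 prime signal of the actin and Gapdh controls was 4.48 in both arrays numbered 1 and 3.95 and 3.91 in those numbered 2. Most of this lay in Gapdh, at 5.35 and 5.27 against 4.56 and 4.30. Actin was at 3.61 and 3.69 against 3.34 and 3.52. With 2 control genes, whether RNA or amplification quality differed with the number is not settled. Camera passed 12 of the 31 lists in this split at its preset correlation and 0 with an estimated correlation, and 0 by either in the crossed split.

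The immediate early and dissociation list differed by −0.965 between the numbers, by −0.98 in the TCDD arrays and −0.95 in the DMSO arrays, and did not pass with an estimated correlation. The deposited normalisation stays open as a source: quantile normalising the columns again left −0.948, but moved values by only 0.018 on average and so decides nothing. Handling or dissociation of the spleens that differed between the numbers stays open: the heat shock list, also raised by handling, differed by −0.117 between the numbers, at −0.271 in the TCDD arrays and 0.037 in the DMSO arrays. The difference in 3 prime signal stays open beside it. No biological explanation was tested, as the design gives the numbers no meaning.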
